A study of Homo sapiens with 24 samples.

How the data were processed

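RNA of 3 anaplastic large cell lymphoma (ALCL) cell lines, DEL, FEPD and K299, was measured on Illumina expression BeadChips, 1 array per line, induction state and duration, 24 arrays in all. Per the labels' protocols, the lines were transduced with a retrovirus carrying a short hairpin RNA against IRF4, selected with puromycin, and the hairpin was switched on by doxycycline. Total RNA was amplified and biotin-labelled before hybridisation, per the labels. The 24 arrays formed 6 groups of 4, each line not induced and induced, with 24, 48, 72 and 96 h as the 4 members of a group. Each induced array had its own control array of the same line and duration, giving 12 pairs, and no control array was shared.

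The deposited value table held log2 expression values of 47309 probes, and what the authors did to make it is not given in the sources used here. Its array medians lay between 5.18 and 5.28 and its lowest values near 4, and the sorted columns differed from their common mean by at most 0.226, so the arrays were close to 1 distribution without being on it. Missing values (412, in 190 probes) fell in the same probes of both arrays of every pair, and those probes were left out. The deposited scanner files held the intensity of each single bead on a linear scale, with a numeric code per bead type. No table used here joins these codes to probe names, so the scanner files gave quality values and counts without gene names. Their upper quantiles matched those of the value table (95% quantile 12.01 in the scanner files and 11.96 in the table, in log2), whereas the medians were 7.09 and 5.22, so that the table's dim values had been lowered by a step that is not stated.

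Each array carried 954618 to 1081170 beads over 48324 bead types, with a median of 20 to 22 beads per type, and the median standard error of a bead type was 0.0943 to 0.104 in log2. This error covers the beads of 1 array only, and the number of arrays limits the precision of every comparison. Array-to-array correlations from the scanner files and from the table, over all 276 pairs of arrays, correlated at 0.997. Within a line this correlation was 0.913 in DEL, 0.970 in FEPD and 0.792 in K299. Of 84 exchanges of 2 arrays within a line, 3 raised the mean of these within-line values. No 2 arrays were copies of each other: at most 0.00424% of probes had exactly equal values in 2 arrays.

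The value table was quantile normalised across the 24 arrays. Probes were named from GEO's platform annotation, with symbols updated through Entrez identifiers to RefSeq symbols. Of the probes, 30108 had 1 symbol, 8 had several and 17193 had none, and 30069 identifiers matched RefSeq. A probe was kept when its mean over the 8 arrays of at least 1 line exceeded the median of all values (5.22). Each gene was represented by its probe with the highest mean over all arrays, which left 13456 of 20043 genes. Of these, 3762 had more than 1 passing probe.

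Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the pair of arrays as a fixed block and 1 induction term for all pairs, 1 per line, 1 per duration, or line terms plus a slope per 24 h. The difference between lines was the F-test over the line terms. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The pair block follows from the series' design, which sets each induced array against its own control. Deviations from the group means correlated between the arrays of a pair at 0.253 to 0.649 in 11 of 12 pairs, and at -0.0470 in the FEPD 24 h pair. Gene lists (36, of at least 5 measured members) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. An exact sign-flip permutation test of each list's mean over the 12 pairs (two-sided, 4096 sign patterns) was added after the data were examined. Designs, gene lists, other settings and the rule for named genes were fixed before the data were examined.

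Named genes were IRF4 and MYC, the 10 raised and 10 lowered genes of largest fold over all lines with the same sign in at least 11 of 12 pairs, 5 and 5 per line with the same sign in 4 of 4 pairs, 2 and 2 per duration, 6 for the line difference, and members of the lists. Open reading frame, predicted and LOC names were passed over.

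The fits were tested on simulated data with the real means and spreads of 13456 genes, 200 of them changed. For a log2 change of 0.5, 83.0% of the changed genes were recovered over all lines, 18.5% in DEL, 5.0% in FEPD, 0 in K299 and 0 at 24 h. All lines were simulated with the same spread per gene and a single draw per setting. Differences between lines in these shares therefore come from the draw and do not show which line had more power. For a log2 change of 1, 100% were recovered over all lines, 93.5% in DEL, 94.5% in FEPD, 93.0% in K299, 86.0% at 24 h and 82.5% at 96 h, and 66.5% for a change in 1 line in the line difference. For a slope of 0.5 per 24 h, 89.5% were recovered. A simulated list of 20 genes shifted by 0.3 was called, and 0 of the other 35 were. Noise was drawn independently for each gene, so this says nothing about false list calls when genes of a list are correlated.

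Alternatives covered the pair block, scaling, the filter on dim probes, the probe per gene, the pseudocount, the moderation, array weights, the unit of replication, and leaving out lines, durations and pairs. Each line lay on its own chip, with both states of a duration in neighbouring sections, always in the same order, so that line cannot be told apart from chip, nor induction from section. No array of cells with doxycycline and another hairpin, or with doxycycline alone, was used here. Bead files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.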

Results

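The arrays addressed what follows in ALCL cells when the transcription factor IRF4 is lowered, a question that the series' title links to MYC signalling and survival. ALCL is a T cell lymphoma, and as background DEL and K299 carry ALK fusions whereas FEPD does not. For each of the 3 lines there were 4 not-induced and 4 induced arrays, at 24, 48, 72 and 96 h. Durations stood in for replicates within a line, and lines for replicates at a duration, since there was 1 array per line, state and duration. The labels do not say that arrays came from separate cultures, so p-values measure the spread between these samples, which may be partly technical. Log2 ratios are induced against not induced, with SE from limma unless SD is given.

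IRF4, the target of the hairpin, was lower in 11 of 12 induced arrays than in their controls, at 72.3% of the control level (mean log2 ratio -0.47 ± 0.30, SD, n = 12, exact sign-flip permutation p = 0.000977, two-sided). The mean log2 ratio was -0.52 ± 0.17 in DEL, -0.26 ± 0.31 in FEPD and -0.62 ± 0.32 in K299 (SD, n = 4 each). In the array labelled induced at 72 h in FEPD, IRF4 was 0.11 higher than in its control, against the label. In a line, 4 pairs allow no exact p below 0.125, which DEL and K299 reached and FEPD (0.25) did not. The limma fit over all pairs gave an adjusted p of 0.00607 for IRF4, and no single line passed (adjusted p = 0.069 in DEL, 0.54 in FEPD and 0.0629 in K299). The limma call was lost without the 96 h arrays (adjusted p = 0.0632), without DEL (0.126), without K299 (0.0995) and with the 3 line means as replicates (0.238).

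MYC, the transcription factor named in the series' title, was at 84.7% of the control level over all pairs (log2 ratio -0.24 ± 0.28, SD, n = 12, lower in 9 of 12, exact permutation p = 0.0103), which did not pass the limma test over all genes (adjusted p = 0.154). It was lower in 4 of 4 pairs of DEL (-0.37 ± 0.31, SD) and of K299 (-0.35 ± 0.21, SD), and at 99.9% of the control level in FEPD. A second, dimmer MYC probe gave -0.18 ± 0.30 over the 12 pairs (SD, exact permutation p = 0.0684), with -0.33 in DEL, -0.12 in FEPD and -0.08 in K299, so the probes differed in K299.

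**Figure D1:**
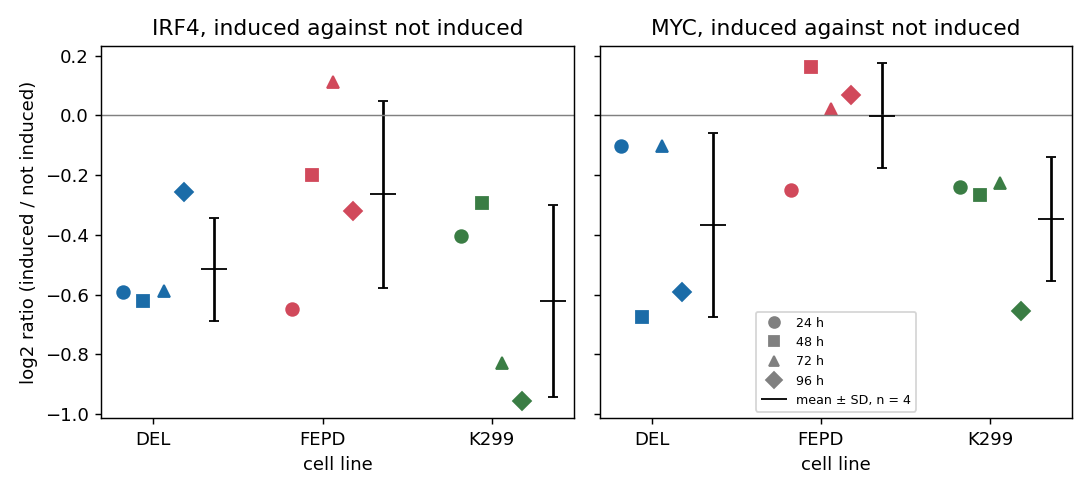
Log2 ratio of IRF4 (left) and MYC (right) in each of the 12 pairs of arrays, by cell line on the x axis, with symbols for the duration and black bars for the mean ± SD of 4 pairs. IRF4 lies below 0 in 11 of 12 pairs and MYC in 9 of 12, and the FEPD mean of MYC is at 0.

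Over all lines and durations, the lists of cytotoxic granule genes and of histones were higher and those of MYC target and ribosome biogenesis genes lower, although most members of each did not pass the test on their own. Among called genes with the same sign in at least 11 of 12 pairs, the largest increases were those of PHLDA1 (1.22 ± 0.19), CD300C (1.04 ± 0.19), an immunoglobulin-like receptor of leukocytes, PRDM8 (1.03 ± 0.19) and IL7R (1.01 ± 0.21), the interleukin 7 receptor. ARHGAP9 (0.91 ± 0.15), H4C8 (0.87 ± 0.12), GZMB (granzyme B, 0.86 ± 0.14), OAS3 (0.83 ± 0.11), an interferon-induced antiviral enzyme, H2AC6 (0.83 ± 0.13) and ID2 (0.82 ± 0.15), an inhibitor of basic helix-loop-helix factors, followed. The largest decreases among such genes were those of HES7 (-0.83 ± 0.14), GNPDA1 (-0.82 ± 0.07), an enzyme of glucosamine metabolism, PIK3R6 (-0.76 ± 0.09), a regulatory subunit of phosphoinositide 3-kinase gamma, CTTN (cortactin, -0.71 ± 0.10) and the DNA repair gene ERCC4 (-0.71 ± 0.16). SOX2-OT, a noncoding RNA whose gene overlaps SOX2 (-0.67 ± 0.12), PTMA (-0.66 ± 0.11), BBS2 (-0.61 ± 0.12), SLC16A7 (-0.58 ± 0.11) and CAPN14 (-0.55 ± 0.11) were also lower. Probes disagreed for PHLDA1, whose dimmer probe gave 0.53 (adjusted p = 0.053 in limma over every probe). The dimmer probes of ARHGAP9 (0.45, adjusted p = 0.0403) and SLC16A7 (-0.38, adjusted p = 0.0425) also gave smaller changes. GNPDA1 had the smallest adjusted p (2.33e-06) and, with PIK3R6 and CTTN, was lower in 12 of 12 pairs.

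Of 13456 genes, 291 were called (185 higher, 106 lower; limma with the pairs as blocks), 66 of them with the same sign in 12 of 12 pairs. The count was 120 with no replicate block, 84, 73 and 46 without the 48, 72 or 96 h arrays, 62 without DEL and 126 without K299. With 3 line means as replicates it was 0 in limma, so the calls describe these pairs and not lines at large.

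**Figure D2:**
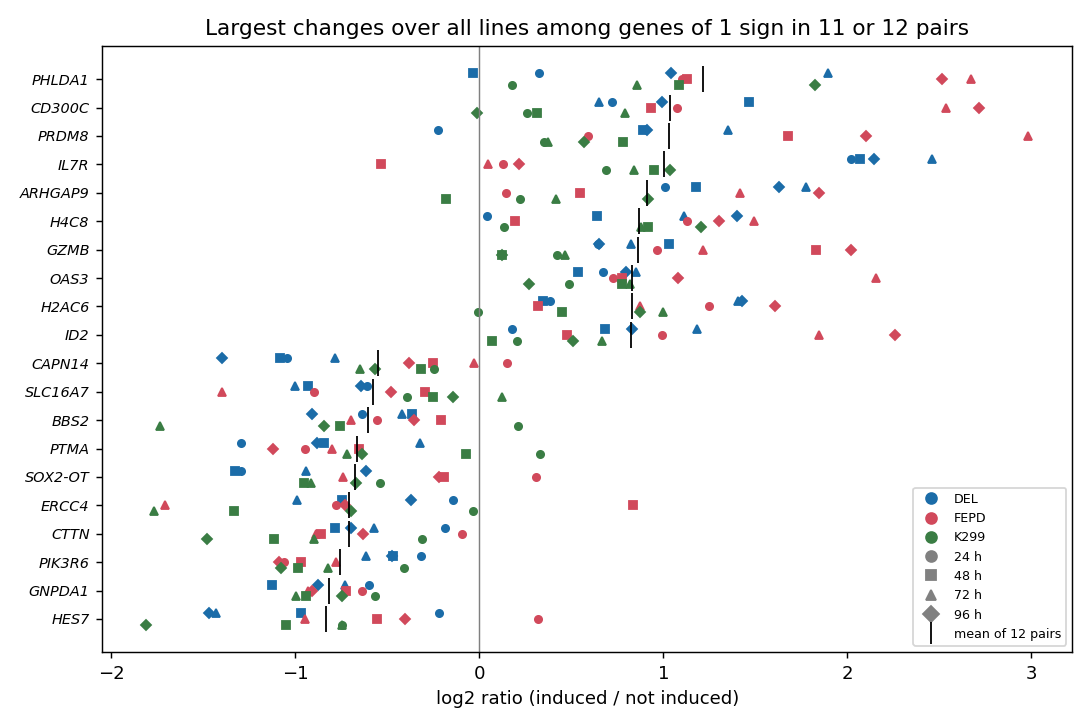
Log2 ratio (x axis) of 20 genes (y axis), with 1 symbol per pair of arrays, coloured by line and shaped by duration, and a black bar at the mean of 12 pairs. They are the 10 raised and 10 lowered most over all lines among called genes with the same sign in at least 11 of 12 pairs. GNPDA1, PIK3R6 and CTTN lie below 0 in all 12 pairs, and GZMB, OAS3, ID2 and H4C8 above 0 in all 12.

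Of the replication-dependent histones, whose messages accompany DNA synthesis, 9 of 20 measured genes rose and none fell (14 when adjusted over the list alone), with a median log2 change of 0.40. H2BC12 (0.66), H2AC18 (0.72) and H2BC5 (0.71) were among them. Members of this family are near-identical in sequence, so a probe can also read a relative. Whether the amplification captured the messages made in S phase or other transcripts of these genes was not tested. The list was higher in 11 of 12 pairs (camera adjusted p = 1.41e-16; adjusted p = 0.0248 with an estimated correlation, or 0.0646 without the FEPD 24 h pair; exact permutation adjusted p = 0.00879). Genes of DNA replication and S phase went the other way as a list, with a median of -0.13 over 36 genes, of which 0 were called (camera adjusted p = 0.000112; adjusted p = 0.0719 with an estimated correlation).

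Of 39 measured MYC target genes, 2 fell and none rose (14 fell when adjusted over the list alone): PPAN, a ribosome assembly factor (-0.44, adjusted p = 0.0044), and PUS1, a pseudouridine synthase (-0.29, adjusted p = 0.0387). The list's mean was below that of all genes in 12 of 12 pairs (camera adjusted p = 1.56e-11; adjusted p = 0.0476 with an estimated correlation, or 0.105 without the FEPD 24 h pair; exact permutation adjusted p = 0.00586). Of 40 ribosome biogenesis genes 2 fell, HEATR1 (-0.38) and UTP15 (-0.43), 9 when adjusted over the list alone, and the list was lower in 12 of 12 pairs (camera adjusted p = 1.08e-09; adjusted p = 0.0248 with an estimated correlation, or 0.0646 without the FEPD 24 h pair). Genes of the cytosolic ribosomal proteins gave a median of 0.00 (camera adjusted p = 0.788).

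Of 14 measured cytotoxic granule genes, 4 rose and none fell (6 when adjusted over the list alone). These were GZMB, PRF1 (perforin, 0.69), CST7 (0.59) and SRGN (serglycin, 0.40). The list was higher in 12 of 12 pairs (camera adjusted p = 3.17e-07; adjusted p = 0.0248 with an estimated correlation, or 0.0646 without the FEPD 24 h pair; exact permutation adjusted p = 0.00586). Of 8 markers of NK cells, which share granule genes with cytotoxic T cells, 2 rose, KIR3DL1 (0.40) and KIR2DL1 (0.29), with adjusted p = 0.0719 with an estimated correlation. Of 42 interferon-stimulated genes 3 rose, OAS3, GBP1 (0.60) and IFI44 (0.53), 7 when adjusted over the list alone beside 1 that fell, and the list's call (camera adjusted p = 3e-05) was lost at adjusted p = 0.0719 with an estimated correlation. In DEL 1 of them rose, OAS3 (0.71), and 2 fell, IFIT2 (-0.81) and ISG20 (-0.87), 5 and 5 when adjusted over the list alone, and the list's median (0.039) and mean (-0.009) differed in sign (camera adjusted p = 0.897). FEPD exceeded DEL by a median of 0.23 (camera adjusted p = 0.00127; adjusted p = 0.444 with an estimated correlation). Against all genes the list's mean was 0.23 in FEPD, 0.19 in K299 and -0.011 in DEL. Single pairs overlapped, with a mean log2 ratio at 24 h of 0.091 in DEL and 0.051 in K299. Whether DEL stood apart from the other lines therefore stays open.

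**Figure D3:**
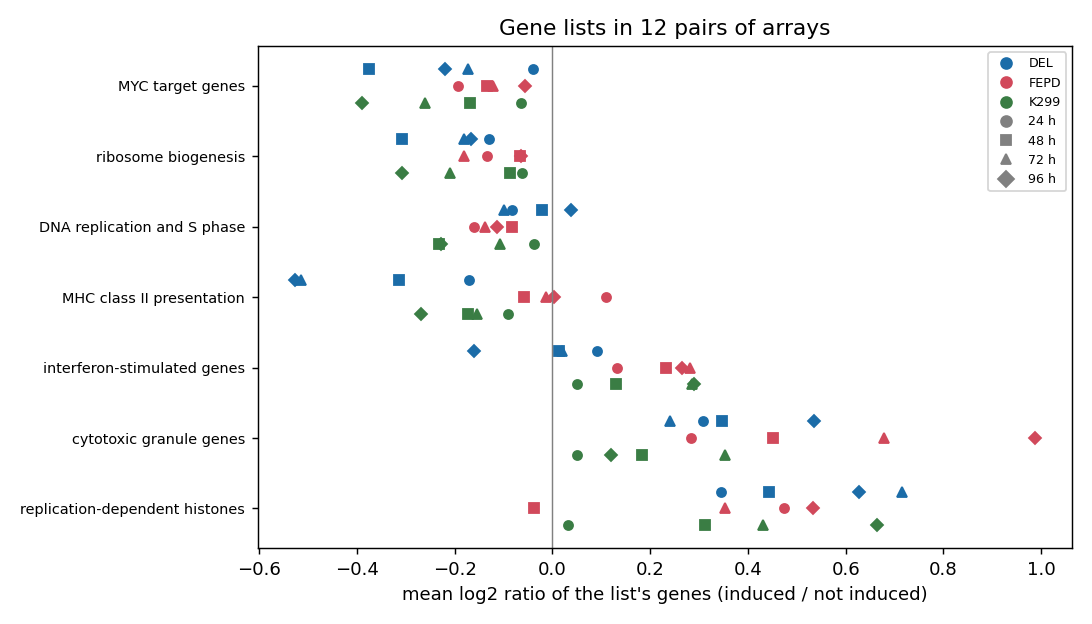
Mean log2 ratio of the genes of 7 lists (x axis; lists on the y axis) in each of the 12 pairs, coloured by line and shaped by duration. MYC target genes and ribosome biogenesis genes lie below 0 and cytotoxic granule genes above 0 in all 12 pairs.

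Camera called 15 of 36 lists over all lines. Histones, MYC target genes, ribosome biogenesis and cytotoxic granule genes were the 4 that held with an estimated correlation. Without the FEPD 24 h pair none of the 4 did (adjusted p = 0.105 for MYC target genes and 0.0646 for the other lists), and without the FEPD 72 h pair the MYC target genes did not (0.074). The other pairs were not left out in this test, so the loss need not be particular to FEPD. Without the genes called over all lines, none of the 4 held either (0.142 for MYC target genes, 0.139 for ribosome biogenesis, 0.184 for histones and for granule genes). Taking out a list's strongest members weakens it by construction, so this loss says little about the lists. Camera at the preset correlation still called all 4 (adjusted p = 1.34e-09, 5.9e-08, 0.00185 and 0.012 in the same order). The other 11 were the interferon-stimulated and DNA replication genes above, MHC class II presentation (median -0.16; adjusted p = 0.156 with an estimated correlation), cell cycle inhibitors (0.11; 0.0768), nucleotide synthesis (-0.10; 0.152), heat shock and proteasome (-0.09; 0.224), mitochondrial ribosome (-0.09; 0.362), NK cell markers (0.31; 0.0719), adhesion (0.08; 0.128), autophagy and lysosome (0.03; 0.165) and apoptosis regulators (0.06; 0.108), where the second value in brackets is the adjusted p with an estimated correlation. Within these lists CDKN1A, the cyclin-dependent kinase inhibitor p21 (0.38), CFLAR (0.57) and TNFSF10 (TRAIL, 0.56), which act in death receptor signalling, CTSB (0.56) and ANXA1 (0.36) rose and HSPH1 (-0.38) fell. Among lists that were not called, IL2RA (-0.41), CCR7 (-0.80) and the B cell factor EBF1 (-0.78) fell, whereas SERPINA1 (0.42), PIM1 (0.48), IL4R (0.36), MXD1 (0.71), a MYC antagonist, GADD45A (0.43) and BATF (0.50) rose. Of the markers of other cell types, CD68 (0.58) and ITGAX (0.51) rose and S100A9 (-0.44) fell among 13 myeloid genes (list adjusted p = 0.757 in camera). The 21 lists that camera did not call had adjusted p from 0.0526 to 0.995, glycolysis, oxidative phosphorylation and the integrated stress response among them. With the genes called over all lines taken out of the lists, camera no longer called NK cell markers, apoptosis regulators (adjusted p = 0.384 each) or autophagy and lysosome (0.074).

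In DEL, MIR155HG, the host gene of microRNA 155, rose most (log2 ratio 2.80 ± 0.22), followed by IL7R (2.17 ± 0.14), RGS18 (1.98 ± 0.19), IL1RN, the interleukin 1 receptor antagonist (1.73 ± 0.24), and SLAMF8 (1.70 ± 0.17). TCHHL1 (-2.08 ± 0.16), TIMD4 (-1.81 ± 0.18), CRABP2, a retinoic acid binding protein (-1.81 ± 0.20), ZBED2 (-1.78 ± 0.15) and MEGF6 (-1.70 ± 0.19) fell most. A second probe of IL1RN gave 0.98 (adjusted p = 0.0606 in limma over every probe). Of 13 MHC class II genes, 3 fell (8 when adjusted over the list alone), HLA-DMB (-0.84), HLA-DPB1 (-0.75) and HLA-DRB1 (-0.57), and this was the only list called in a single line with an estimated correlation (adjusted p = 0.0478; camera adjusted p = 4.23e-07). In DEL 8 histones, and of the granule genes GZMB, CST7 (0.83), GZMA (1.5) and SRGN (0.71), rose. In all, 321 genes were called (201 higher, 120 lower; limma, n = 4 pairs), 112 with no replicate block, and 122, 158 and 149 without the 48, 72 or 96 h pair.

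In FEPD, the granule gene NKG7 (2.70 ± 0.22) rose most, followed by ITGB7, an integrin chain (2.04 ± 0.32), the granule gene GZMH (2.01 ± 0.28), CD93 (2.0 ± 0.25) and PHLDA1 (1.85 ± 0.29). MEOX1 (-1.17 ± 0.16), KDM7A (-1.06 ± 0.17), the noncoding RNA LINC00887 (-1.0 ± 0.17), PIK3R6 (-0.97 ± 0.13) and NIM1K (-0.91 ± 0.19) had the largest decreases among genes lower in 4 of 4 pairs. Not-induced CD93 (5.31) and induced NIM1K (5.37) lay near the filter's level of 5.22, so the size of their changes is not exact. Second probes gave 0.39 for PHLDA1 and -0.40 for MEOX1 (adjusted p = 0.629 and 0.239 in limma over every probe). GZMB (1.51) and PRF1 (1.18) were among the 4 of 14 granule genes that rose, with adjusted p = 0.0988 for the list with an estimated correlation. Of the interferon-stimulated genes 5 rose, among them OAS3 (1.18), IFI44 (0.92) and GBP4 (1.07), with adjusted p = 0.0962 for the list with an estimated correlation. In all, 174 genes were called (123 higher, 51 lower; limma, n = 4 pairs), 70 with no replicate block, 51 when fitted on the 8 FEPD arrays, 280 without the 24 h pair and 89, 61 and 50 without the 48, 72 or 96 h pair. The direction includes the 72 h pair, in which IRF4 went against its label, and the 24 h pair had ratios that correlated at -0.0789 on average with those of the other FEPD pairs.

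In K299, IGF2BP3, an RNA-binding protein (1.52 ± 0.16), IL1RN (1.25 ± 0.24), ITGA1, the integrin alpha 1 chain (1.24 ± 0.16), DYSF (0.99 ± 0.16) and FYB1 (0.96 ± 0.15) rose most. The urate transporter gene SLC2A9 (-1.21 ± 0.16), HES7 (-1.09 ± 0.21), UTS2B (-1.06 ± 0.15), SOX2 (-1.03 ± 0.22) and ZBED2 (-1.02 ± 0.15) fell most. PPAN fell (-0.60) and the MYC target list had a median of -0.22 (camera adjusted p = 1.45e-08; adjusted p = 0.105 with an estimated correlation). The list's mean was -0.065, -0.17, -0.26 and -0.39 at 24, 48, 72 and 96 h, with 1 pair at each. In FEPD the order was the reverse (-0.19, -0.13, -0.12 and -0.057). DEL showed no order (-0.039, -0.38, -0.17 and -0.22). The 96 h pair of K299 also stood apart in the integrated stress response list (0.91). In all, 67 genes were called (34 higher, 33 lower; limma, n = 4 pairs), 15 with no replicate block, 29 when fitted on the 8 K299 arrays, and 19, 4 and 6 without the 48, 72 or 96 h pair.

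The widest measured differences between lines were those of MIR155HG, IL21R, NKG7, IL7R, ITGB7 and GZMH. MIR155HG was at 2.80 in DEL, 0.48 in K299 and 0.05 in FEPD (limma F-test, adjusted p = 5.86e-05), and IL7R was at 2.17, 0.88 and -0.03 (adjusted p = 1.66e-05). NKG7 was at 2.70 in FEPD, 0.26 in DEL and 0.21 in K299 (adjusted p = 0.00011), and IL21R at 1.63 in FEPD, -0.06 in K299 and -0.87 in DEL (adjusted p = 0.000619). ITGB7 (adjusted p = 0.0338) and GZMH (adjusted p = 0.007) were raised in FEPD, with -0.13 and -0.02 in DEL. The IL21R difference rests on 1 probe, since 2 dimmer probes gave -0.036 and -0.033 in FEPD and -0.0029 and -0.13 in DEL. MIR155HG and IL7R in FEPD and GZMH in DEL and K299 lay below the level of the filter on dim probes (5.22) in both states, where a change need not show, so the order of these differences is not exact. In all, 137 genes were called, 30 with no replicate block, and 33, 29 and 33 without the 48, 72 or 96 h arrays. Of the lists, MHC class II was higher in FEPD than in DEL by a median of 0.43 (camera adjusted p = 3.24e-05; adjusted p = 0.107 with an estimated correlation).

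**Figure D4:**
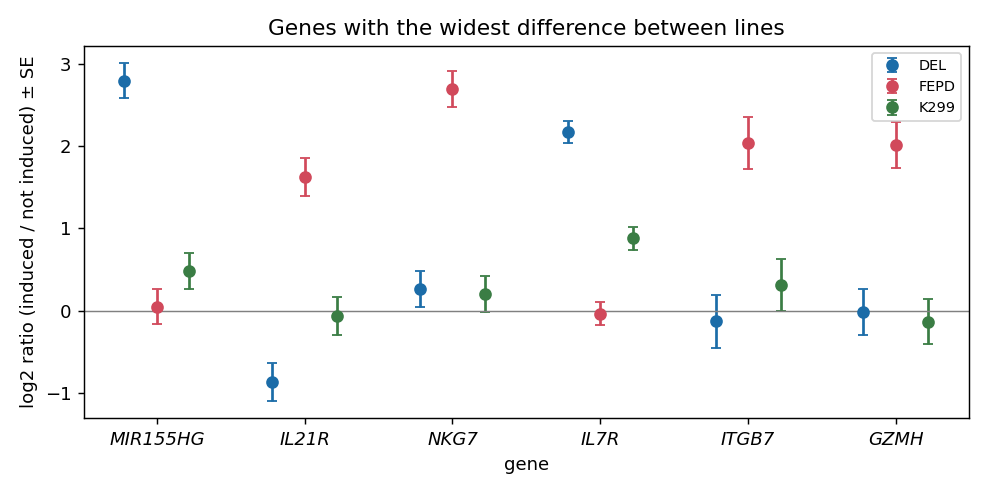
Log2 ratio ± SE from limma (y axis) in each of the 3 lines for the 6 genes (x axis) with the widest difference between lines. MIR155HG and IL7R are highest in DEL, and IL21R, NKG7, ITGB7 and GZMH in FEPD.

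GNPDA1 was the only gene called in all 3 lines (-0.83 in DEL, -0.80 in FEPD, -0.81 in K299). DEL and FEPD shared 15 raised genes, among them GZMB, OAS3, CD68 and H4C8, where 1.84 were expected for independent calls, and 6 lowered genes including KLF2 and PTMA (0.455 expected). DEL and K299 shared 4 raised genes, IL1RN, IL7R, NLRP7 and TGM2 (0.508 expected), and 13 lowered genes including CCR7, SOX2, EOMES, HES7 and PPAN (0.294 expected; Fisher's exact test, adjusted p = 3.43e-18 across genes). FEPD and K299 shared KIR3DL2 upward, an overlap that did not pass the test (0.311 expected, adjusted p = 0.268), and GNPDA1 and PIK3R6 downward (0.125 expected, adjusted p = 0.00828; Fisher's exact test). The lines shared 1 estimate of each gene's spread in the fit, so their calls are not independent. The expected counts may therefore be too low and the p-values of Fisher's test too small. Across genes, which are not independent replicates, line effects correlated at 0.183 for DEL and FEPD, 0.267 for DEL and K299 and 0.145 for FEPD and K299.

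At single durations, with 3 lines each, only 96 h had called genes. PHLDA1 (1.79 ± 0.31), CHODL (1.54 ± 0.23), ARHGAP9 (1.46 ± 0.27), H2AC6 (1.30 ± 0.21) and H4C8 (1.30 ± 0.20) were higher, and CTTN (-0.94 ± 0.17) and GNPDA1 (-0.84 ± 0.14) lower, among 10 called genes (8 higher, 2 lower; limma). Second probes gave 0.54 for PHLDA1 and -1.43 for CTTN at 96 h (adjusted p = 0.76 and 0.0799 in limma over every probe). The 96 h count was 1 with no replicate block and 0 on its own 6 arrays, without DEL or without K299. At 24, 48 and 72 h limma called 0 genes, with 639, 721 and 1080 at an unadjusted p below 0.05. At 72 h it called 5 as deposited or with median scaling, 9 with a stricter filter on dim probes and 23 with trended robust moderation. For the slope over duration limma called 0 genes, with 690 at an unadjusted p below 0.05, so no gene was shown to change its response with time. Histones (median slope 0.11 per 24 h) and granule genes (0.08) were called by camera (adjusted p = 1.18e-06 and 0.00181) but had adjusted p = 0.2 and 0.2 with an estimated correlation.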

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

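Tests of doxycycline acting through mitochondrial translation, of MYC mRNA, of MYC in FEPD, of S phase and of single pairs of arrays were chosen after the results they bear on were seen.

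GNPDA1 was lower in 12 of 12 induced arrays and PIK3R6 in 12, whereas IRF4 was lower in 11. A dependence on IRF4 stays open, as the mean ratio of both genes and the ratio of IRF4 correlated over the 12 pairs at r = -0.0206 (permutation p = 0.948, Spearman's rho 0.0559, permutation p = 0.869; adjusted over 4 relations 0.948 and 0.869), at -0.0868 without the 2 pairs farthest from the median of IRF4 and at 0.195 with each line's mean taken away, and IRF4 moved little. A faulty probe is argued against for PIK3R6, whose other probe changed by -0.68, and stays open for GNPDA1, which had 0 other probes. Doxycycline or an off-target effect of the hairpin may act on both genes and cannot be told apart from the fall of IRF4, since every induced array had all of them. The integrated stress response list, which would rise if doxycycline acted through mitochondrial translation, had a median of -0.022 and a mean of 0.012, which decides nothing, since the K299 96 h pair stood apart at 0.91 and the other 11 pairs lay between -0.18 and 0.05.

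The MYC target list was lower in 12 of 12 pairs. Brightness of its genes as the whole reason is argued against, since its mean lay above 0% of 10000 random lists matched on level. Under the other scalings the largest camera adjusted p was 2.45e-11, which leaves the scaling between arrays open. Median scaling shifts all genes of an array alike, to which a comparison with other genes hardly responds. The deposited arrays were also already close to 1 distribution. A fall of MYC mRNA is a candidate explanation for part of the pattern, as the list's mean and MYC correlated over the 12 pairs at r = 0.793 (permutation p = 0.00262, adjusted over 4 relations 0.0105; Spearman's rho 0.699, permutation p = 0.0149, adjusted 0.0596), and at 0.785 with lines centred (permutation p = 0.0049). Without the 2 pairs farthest from the median of MYC, DEL at 48 h and K299 at 96 h, r was 0.517 (permutation p = 0.124), so the relation leans on those pairs. The K299 96 h pair also stood apart in the integrated stress response list (0.91). At 48, 72 and 96 h in FEPD the MYC target list was lower (-0.13, -0.12 and -0.057) where MYC was not (0.16, 0.02 and 0.067). Over FEPD the brighter MYC probe had a mean of -0.0011 and the dimmer 1 of -0.12, which leaves that line open, as do chip section, doxycycline and off-target effects for every line.

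The histone list was higher in 11 of 12 pairs. Brightness of its genes as the whole reason is argued against, since its mean lay above 100% of the matched random lists. Members correlated at 0.219 on average over the 12 pairs, below the limit fixed beforehand as speaking against 1 transcript read by all probes. Noise in single ratios also lowers this value, and no reference for probes of 1 transcript was measured, so that reading stays open. More cells in S phase is argued against by the DNA replication list, which had a median of -0.13 and was lower in 11 of 12 pairs (fry adjusted p = 0.00377, exact permutation adjusted p = 0.00879, camera adjusted p = 0.0719 with an estimated correlation, which did not pass). In DEL, where the histone mean was highest (0.53 against all genes), that of the replication list was only -0.044. At 96 h in DEL the replication list had a mean log2 ratio of 0.038 and the histones 0.63, so DEL by itself stays open. An effect of the hairpin, of doxycycline or of chip section may remain, and these were not tested apart.

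Chance was examined by regrouping the arrays, which takes them as separate samples, although the labels do not say that they were. With the pairs taken as separate samples, chance was argued against over all lines. Of 100 sign patterns of the pairs 1, the real one, gave 291 genes, and the highest other gave 3. For the line difference chance was argued against on the same terms (1 of 100, with 137 genes and the highest other 63). Neither test covers durations of a line that share a culture. With the 3 line means as replicates limma called 0 genes over all lines. For the gene lists 1 of 100 patterns, the real one, gave 15 lists. The highest other pattern gave 14 and the median was 4, so camera with a preset correlation called lists under patterns other than induction. The count of lists therefore does not exclude chance. Within a line, 8 splits part all 4 pairs, too few for a share below 0.05. Among these, the real count and the highest other were 321 and 2 in DEL, 174 and 188 in FEPD and 67 and 1 in K299. The 188 came from exchanging the labels of the 24 h pair, in which IRF4 nevertheless followed its label (-0.65). Splits that part fewer pairs reached 74, 165 and 62, and over all 32 splits a count as large came up 1 time in DEL and K299 and 2 times in FEPD, the real split included. For the slope over duration the count was 0, so that 100 of 100 regroupings were bound to give as many (highest other 1), which says nothing about chance. At a single duration 10 splits are too few for a share below 0.05. The real count and the highest other were 0 and 0 at 24 h, 0 and 0 at 48 h, 0 and 104 at 72 h and 10 and 8 at 96 h. The 104 at 72 h came from splits that part the FEPD pair alone, so they set 1 pair against the spread of the other pairs. They may point to a structure of those arrays, which was not tested.

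Among 48 sets of 4 values, 5 held 1 that stood apart from the others by Dixon's test, where chance gives about 1 in 20. These were the MYC level of the FEPD control at 72 h (13.19), the IRF4 level of induced DEL at 48 h (10.54), the number of beads of induced DEL at 72 h (954618), the IRF4 ratio of DEL at 96 h (-0.26) and the MYC ratio of K299 at 96 h (-0.66).

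Of the named genes, 26 differed between lines in limma's F-test. The range of the 3 line effects in log2 was 2.75 for MIR155HG, 2.5 for IL21R, 2.49 for NKG7, 2.21 for IL7R, 2.17 for ITGB7, 2.15 for GZMH, 2.14 for TCHHL1, 2.03 for ZBED2, 1.98 for RGS18, 1.97 for TIMD4, 1.91 for CD93 and 1.77 for CRABP2. It was 1.69 for KDM7A, 1.67 for SLAMF8, 1.64 for IGF2BP3, 1.58 for MEGF6, 1.41 for SLC2A9, 1.38 for NIM1K, 1.38 for MEOX1, 1.33 for ITGA1, 1.23 for GZMB, 1.18 for DYSF, 1.08 for LINC00887, 1.05 for UTS2B, 0.95 for CAPN14 and 0.93 for FYB1. Of these genes, 16 lay below the level of the filter on dim probes (5.22) in both states of at least 1 line, where a change need not show, so their ranges are not exact. They were IL7R, MIR155HG, RGS18, SLAMF8, GZMH, IGF2BP3, ITGA1, FYB1, CAPN14, TCHHL1, TIMD4, MEGF6, MEOX1, LINC00887, SLC2A9 and UTS2B. The range of IL21R rests on its brightest probe, since its 2 other passing probes gave -0.036 and -0.033 in FEPD. Outside the named genes, 39 of 7739 probes without 1 gene symbol passed the threshold over all lines. Of 26789 bead types of the scanner measurements, which carry no gene names and so were not parted from the named genes, 457 passed.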

How the results depend on the processing

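Tests without single pairs, on bead types and on every probe, and the sign-flip test of the lists, were chosen after the data were seen.

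Of the single genes named, 1057 values under alternatives kept their direction and side of the threshold, 111 kept the direction but lost the call and 0 reversed. Most of these genes were chosen for passing the threshold with the same sign in all or nearly all pairs. Some alternatives, such as line means or a random block, leave the log2 change as it was. The absence of reversals was therefore largely built in and does not show robustness. With 3 line means as replicates all 20 of the called genes named over all lines besides IRF4 lost it. For counts that moved, the cause was not tested, except that leaving out arrays or averaging them leaves fewer samples. With no replicate block limma called 120 genes over all lines, 112 in DEL, 70 in FEPD, 15 in K299, 30 for the line difference and 1 at 96 h, and the IRF4 call stayed. With line means as replicates it called 0, and IRF4, at -0.47, was not called (adjusted p = 0.238). Line as a random block gave 293. Fitted on its own 8 arrays, FEPD gave 51 and K299 29, and 96 h on its own 6 arrays gave 0. At 24 h and for the slope limma called 0 genes under each alternative run.

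Array weights gave 508 in DEL, 294 in FEPD, 158 in K299, 246 for the line difference, 1 at 48 h and 6 at 72 h. At 48 h, where the count was 0, it was 1 with no filter on dim probes, and also with the stricter filter, the mean of probes, 16 added before log2 and a trended robust moderation. At 72 h, where the count was 0, it was 5 as deposited, 5 with median scaling, 9 with the stricter filter, 2 with the mean of probes, 8 with 16 added and 23 with trended robust moderation. At 96 h (10) it was 6 with the mean of probes, 28 with trended robust moderation and 4 over every probe. Bead types gave 457 over all lines, 2 at 48 h, 14 at 72 h and 17 at 96 h. Median scaling moved the FEPD calls from 123 higher and 51 lower to 104 and 74. The correlation of line effects was 0.157 for DEL and FEPD with no filter, and 0.239 with the stricter filter, which gave 0.332 for DEL and K299. Of the 15 lists, 4 were called with an estimated correlation, and the exact sign-flip permutation test called 12, all but heat shock and proteasome (adjusted p = 0.0504), autophagy and lysosome (0.0776) and mitochondrial ribosome (0.15). Over 36 lists it called 14, T helper cytokines and T cell receptor signalling among them.

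Without 1 duration, line or pair, counts ranged over 46 to 417 for all lines, 122 to 358 in DEL, 50 to 280 in FEPD, 4 to 77 in K299, 29 to 140 for the line difference, 0 to 10 at 96 h (0 without DEL and without K299) and 12 to 17 lists. Of single pairs, the count over all lines fell by over 1.5 times without DEL at 24 h (187), 48 h (157), 72 h (165) and 96 h (169), and without K299 at 72 h (174) and 96 h (170). IRF4 ranged over -0.57 to -0.39, and its call was lost without 96 h (adjusted p = 0.0632), DEL (0.126) or K299 (0.0995) in limma. Correlations of line effects ranged over 0.128 to 0.182 for DEL and FEPD, 0.164 to 0.276 for DEL and K299 and 0.0607 to 0.151 for FEPD and K299. Background correction by normexp was not run, since the table's dim values had already been lowered, and IRF4 had 1 probe. Signal over background limits dim genes, which were not tested below a log2 level of 5.22 in every line, and the number of arrays limits all comparisons.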

Other observations

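Genes of these baseline comparisons were chosen after their values were seen. Not-induced arrays of the 3 lines differed in several lineage genes, without a test, since each line lay on its own chip. ALK was at 12.89 ± 0.25 in DEL and 13.19 ± 0.23 in K299 against 5.76 ± 0.14 in FEPD (log2, SD, n = 4). The cytokine gene IL22 was at 14.47 ± 0.16 in FEPD and at 4.97 ± 0.26 and 4.77 ± 0.20 in DEL and K299. SOX2, a stem cell transcription factor, was at 8.42 ± 0.29 in DEL, 9.83 ± 0.76 in K299 and 4.62 ± 0.069 in FEPD.

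Starting levels also differed for genes whose induction effect differed between lines. NKG7, which rose in FEPD, was at 6.92 ± 0.70 in not-induced FEPD and at 13.69 ± 0.28 and 13.29 ± 0.083 in DEL and K299. IL7R, which rose in DEL and K299, was at 5.93 ± 0.60 in DEL, 11.37 ± 0.30 in K299 and 5.20 ± 0.25 in FEPD, below the filter's level of 5.22. TIMD4, which fell in DEL, was at 8.50 ± 0.65 there and at 4.65 ± 0.13 in FEPD and 4.8 ± 0.12 in K299, also below that level. IRF4 itself was at 13.17 ± 0.31 in FEPD and 11.22 ± 0.16 in DEL, with K299 between them.

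Over the 12 pairs the ratios of MYC and IRF4 correlated at r = 0.508 (permutation p = 0.0918, adjusted over 4 relations 0.122) and rho = 0.489 (permutation p = 0.11, adjusted 0.146). That r was 0.22 without the 2 pairs farthest from the median of IRF4 and 0.294 with lines centred. The MYC target list and IRF4 correlated at r = 0.565 (permutation p = 0.0552, adjusted 0.111) and rho = 0.531 (permutation p = 0.08, adjusted 0.146). Here r was 0.391 without those 2 pairs and 0.468 with lines centred. Neither relation passed the threshold.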
